A study of Mus musculus with 4 samples.

How the data were processed

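The series holds 4 GEO samples, an mRNA and a hashtag library from each of 2 capture reactions of 1 pool of dissociated mouse sarcomas. Per the labels' protocols, tumours were dissociated, enriched for CD45-positive cells with magnetic beads, tagged per sample with TotalSeq-A hashtags, pooled in equal proportions at 1000 cells per microlitre and captured with the 10x Genomics 3′ kit version 3, aiming at about 20000 cells. The libraries were sequenced to 800M read pairs, with 5% given to the hashtag library. Per the submitters' processing notes, Cell Ranger (no version given) and Seurat version 4 were used with mm10. The deposited matrices hold UMI counts per gene or hashtag and barcode, with no normalization. They cover 32285 mouse genes, 2 added reporter sequences and 5 hashtags. A deposited table per reaction gives the authors' call of each barcode as sgCTR or sgMif. How the calls were made is not stated, and barcodes without a call are not in it.

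The calls name the genotype and no tumour. The hashtag counts showed hashtag 12 highest in 100% of sgCTR barcodes, and hashtag 1 or 2 highest in 33.8% and 60.4% of sgMif barcodes. Before the data were examined it had been set that with only genotypes named there would be no test, and that values, counting intervals and the value in each reaction would be given. That was kept. After the hashtags were read, sgMif barcodes were divided by the tag that exceeded the other 3-fold, which made 2 sgMif samples, and a test of 1 sgCTR sample against these 2 was added as an alternative. The spread in that test comes from the sgMif pair alone, so the lone sgCTR sample is assumed to vary in the same way. Each hashtag was taken as 1 sample because the labels say that samples were tagged individually. How many animals a sample holds is not stated.

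Barcodes with a call, at least 500 genes and under 10% mitochondrial UMIs were kept, 12732 in all. The deposited matrices hold 23831 barcodes against the target of about 20000 cells. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were chosen, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, python 3.11.15). Clusters were named by the mean scaled level of markers fixed before the data were examined. A leading gene had to be seen in at least 10% of the cluster's cells, a rule added after a single barcode with haemoglobin RNA led a cluster. Every cluster could be named in the reported clustering, while clusters were left unnamed in some alternatives. Macrophages were clustered again at resolution 0.5, also without the genes with at least 50 CPM and 100 UMIs that differed by 1.5-fold in the same direction in each reaction. The distance between samples is the percent of cells that would have to change sub-cluster. No doublet caller was used in the reported values beyond the hashtag calls. Scrublet's automatic threshold marked 1 barcode, so the alternative removed the 8% of barcodes with the highest scores in each reaction.

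UMI counts were summed per class and sample over both reactions. Log2 ratios are of CPM after TMM scaling (edgeR 4.0.16, R 4.3.3) with a prior count of 2. Levels per hashtag sample are CPM with TMM factors of the 3 samples, and CPM in the closing parts are without TMM factors. Named genes were chosen by a rule fixed before the data were examined. It takes Mif, Ddt, Cd74, Cd44 and Cxcr4, then the 10 highest and 10 lowest ratios (5 and 5 outside macrophages and mesenchymal cells) among genes with at least 50 CPM in the higher genotype, at least 100 UMIs and at least 1.5-fold in the same direction in each reaction, then up to 4 members of each described list by largest ratio with at least 50 UMIs. Members of described lists were otherwise picked for their levels after these were seen, as were Arg1, Vegfa, Cxcl1, Cxcl10, Ptn, Retnla, S100a9, Il1r2 and G0s2. The median log2 ratio of each of 23 gene lists fixed beforehand, over members with at least 50 UMIs where 5 or more had them, was placed among 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these sums and is no test across samples.

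Across genes with at least 1000 UMIs, the log2 ratios of both reactions correlated with Pearson's r = 0.943 in macrophages (4355 genes), 0.876 in mesenchymal cells (3600), 0.871 in neutrophils (609), 0.823 in T cells (1408) and 0.714 in NK cells (814). Genes are not independent replicates, and the reactions repeat the capture of the same cells' pool, so this measures technical precision alone.

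The 3-sample test used edgeR's quasi-likelihood model with filterByExpr, TMM and Benjamini-Hochberg adjustment at 0.05, for classes with at least 30 cells in each sample. It was tested on simulated sums with 200 changed genes and the common dispersion fitted to each class (0.150 in macrophages). It recovered 34.8% (neutrophils) to 98.5% (mesenchymal cells) of 8-fold changes, 4.48% to 61.2% of 4-fold changes and 0% to 1.49% of 2-fold changes. The same simulations gave 2 (neutrophils) to 11 (T cells) false calls. Gene lists were tested in it with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated one. Both sgMif samples are compared with the same sgCTR sample. The number of named genes on 1 side was therefore also counted in 200 simulated sets of 3 samples with no difference. These sets used edgeR's common dispersion for every gene, which the genes with extreme ratios need not follow. The list percentile and the clustering distance were also tested on simulated data.

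Alternatives listed beforehand, those of a test or of a sample left out on the condition that the data would allow them, were other normalizations (DESeq2 1.42.0 size factors, total counts), no filter on low counts, DESeq2's Wald test, each reaction and each sgMif hashtag left out, the reaction as a block, mitochondrial limits of 5% and 20%, minimums of 200 and 1000 genes, 4000 variable genes, other resolutions and Scrublet. Added later were mesenchymal cells with few UMIs of 10 immune genes, mesenchymal cells with a reporter UMI, and sub-clusters without genes that differ between any samples. Barcodes without a call (38.9% of barcodes and 29.3% of gene UMIs) enter no comparison.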

Results

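The data are single-cell transcriptomes of a mouse soft-tissue sarcoma, grown under the skin from transformed mesenchymal stem cells that lack p53 and overexpress cyclin E1. The sarcoma cells carried Cas9 with a control guide (sgCTR) or with a guide against Mif, which encodes the cytokine macrophage migration inhibitory factor (sgMif). Tumours were dissociated, partly enriched for CD45-positive immune cells, tagged per sample with hashtag antibodies and pooled. The same pool was captured in 2 reactions, each with an mRNA and a hashtag library, which makes the 4 deposited samples technical repeats of 1 pool. Reaction 1 held 13126 barcodes with 63268217 gene UMIs (median 2048.5 per barcode), and reaction 2 held 10705 barcodes with 65493515 gene UMIs (median 3470). The authors' calls named 5334 barcodes sgCTR and 9215 sgMif, of which 4975 and 7757 passed the cell filters.

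Every sgCTR barcode had hashtag 12 as its highest tag, whereas 3118 sgMif barcodes had hashtag 1 highest, 5563 hashtag 2, 452 the sgCTR tag, hashtag 12, and 82 hashtag 3 or 4. The design was therefore taken to hold 1 sgCTR sample (4975 cells, median 4335 UMIs) and 2 sgMif samples. These had 2208 cells for hashtag 1 (median 2274 UMIs) and 5327 cells for hashtag 2 (median 4817 UMIs). The other 222 sgMif cells were tied to neither tag and enter only the pooled sgMif values. With 1 sgCTR sample no difference between the genotypes has a replicate check. Values are given for each sample, and intervals (exact Poisson for counts, exact binomial for shares, 95%) cover counting error only. Cell classes were called from marker genes fixed beforehand, so that macrophage, for example, stands for macrophage-like cells.

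The first comparison asked whether the target gene Mif (ENSMUSG00000033307, chromosome 10, 75859353 to 75860277 in mm10) was lower in the edited tumour cells. It was not lower in RNA. In mesenchymal cells, the class that holds the sarcoma cells, Mif stood at 1524 CPM (UMI counts scaled to a common library total) in sgCTR, 1529 in sgMif hashtag 1 and 1759 in sgMif hashtag 2, a pooled log2 ratio of sgMif over sgCTR of 0.20 (95% interval 0.17 to 0.23). The ratio was 0.13 in reaction 1 and 0.23 in reaction 2. The hashtag 1 value rests on 44 barcodes, of which 41 carried more counts of hashtag 12, the sgCTR tag, than of hashtag 1. It is therefore no firm value of edited cells. Mif was also higher in sgMif macrophages, at 874 CPM in sgCTR against 1647 and 1009 with hashtags 1 and 2 (log2 ratio 0.39, interval 0.36 to 0.42). T cells (log2 ratio 0.34) and NK cells (0.35) went the same way, and neutrophils were higher with hashtag 1 (1930 against 788 CPM in sgCTR) and lower with hashtag 2 (455). The guide's position is in none of the files, and a 3′ tag that lies outside a small deletion counts the transcript with or without it, so these levels do not check the knockout.

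Among MIF's partners, macrophage Cd74, the MIF receptor chain that is also the MHC class II invariant chain, stood at 5013 CPM in sgCTR, 2685 with hashtag 1 and 8080 with hashtag 2. Macrophage Cd44, a MIF co-receptor, stood at 619 CPM in sgCTR, 718 with hashtag 1 and 451 with hashtag 2 (pooled log2 ratio −0.29), and Cxcr4, another MIF receptor, at 264, 176 and 232 (−0.31). Ddt, a homologue of Mif, had a macrophage log2 ratio of 0.33. In mesenchymal cells the ratios were 0.45 for Ddt, 0.32 for Cd44, −0.30 for Cxcr4 and −0.71 for Cd74, and whether the Cd74 UMIs of these barcodes come from mesenchymal cells is open.

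The cell composition asked how tumour Mif bears on the immune infiltrate. Macrophages made up 50.2% of sgCTR cells (interval 48.8% to 51.6%) and a smaller share of both sgMif samples, 25.5% with hashtag 1 and 36.8% with hashtag 2. The sgMif samples differed in the other large classes. Neutrophils were 68.1% of the hashtag 1 sample (interval 66.1% to 70.1%), 1.93% of the hashtag 2 sample and 10.7% of sgCTR. T cells were 891 of the 4975 sgCTR cells, 47 of 2208 with hashtag 1 and 1386 of 5327 with hashtag 2, and NK cells 8.28%, 0.453% and 11.6%. Mesenchymal cells were 7.70% of sgCTR, 1.99% with hashtag 1 and 11.6% with hashtag 2. Classical dendritic cells of the cDC2 type were 0.683%, 0.226% and 2.67%, and fibroblasts 0.362%, 0.453% and 2.70%. The fibroblasts with hashtag 2 came mostly from 1 reaction, at 5.05% in reaction 1 and 0.604% in reaction 2 (0.615% and 0.148% in sgCTR), so their share is not stable. No B cell was among the 2208 cells of hashtag 1, with an exact binomial upper limit of 0.167% (3 counts of the total would be 0.136%).

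**Figure D1:**
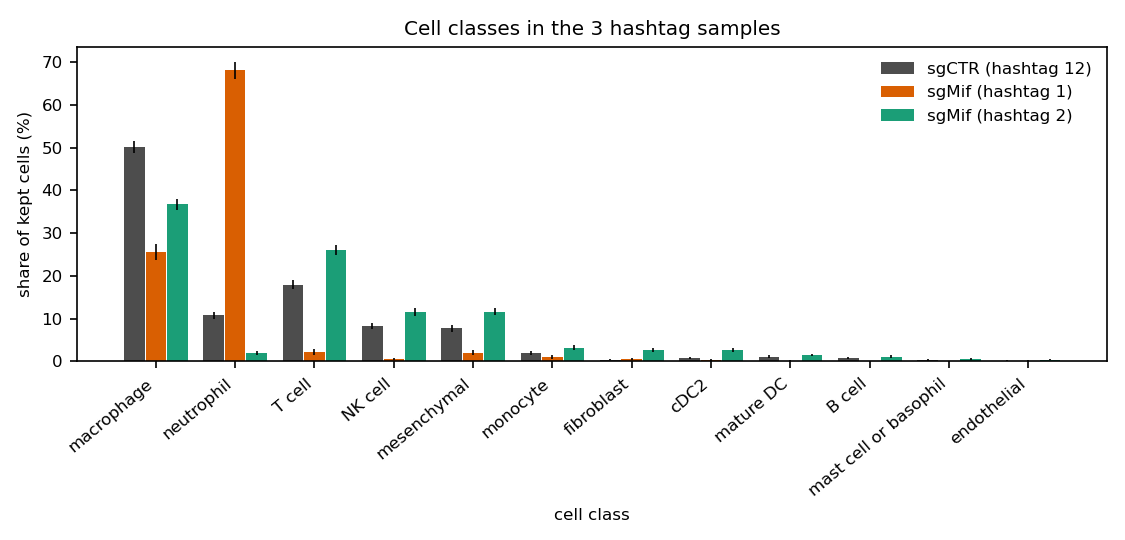
Share of each cell class among the kept cells (percent, y axis) in the sgCTR sample and in both sgMif samples, with exact binomial 95% intervals as error bars. Macrophages were below the 50.2% of sgCTR in both sgMif samples, while neutrophils were 68.1% of one sgMif sample and 1.93% of the other.

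Pooled over all sgMif cells, the share of macrophages was 17.0 points below sgCTR (difference −17.0, interval −18.8 to −15.3) and that of neutrophils 10.4 points above it (interval 9.09 to 11.6). The pooled neutrophil difference came from hashtag 1 alone, since with hashtag 2 alone it was −8.80 points. Among immune cells only, macrophages were 54.7% in sgCTR, 26.2% with hashtag 1 and 43.1% with hashtag 2, and neutrophils 11.7%, 69.9% and 2.27%. The reactions differed by at most 2.39 points in sgCTR, 5.11 in hashtag 1 and 4.45 in hashtag 2 over all classes, the last in fibroblasts. The tumours were enriched for CD45 cells before pooling, which can set the shares of mesenchymal against immune cells, and the minimum of 500 genes removes many neutrophils, whose RNA content is low. With a minimum of 1000 genes the pooled neutrophil difference was 0.148 points, and macrophages were 66.5% of the hashtag 1 sample, 47.5% of sgCTR and 16.6% of the hashtag 2 sample. In that setting clusters without a name held 1.09%, 8.34% and 21.2% of the same samples, so the 16.6% with hashtag 2 is uncertain. The lower macrophage share with hashtag 1 thus depends on how many neutrophils are kept.

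In macrophages, the class the study is about, many genes of lipid handling were lower in both sgMif samples. Lpl, lipoprotein lipase, stood at 2619 CPM in sgCTR, 311 with hashtag 1 and 455 with hashtag 2 (pooled log2 ratio −2.65, interval −2.69 to −2.61). Mfge8, which bridges phagocytes and dying cells, stood at 853, 91.5 and 198 (−2.22), the phospholipid transfer protein Pltp at 312, 52.5 and 77.5 (−2.15), and lysosomal acid lipase Lipa at 410, 154 and 100 (−1.86). Lyz1, a lysozyme, had the lowest ratio (−3.76), with 296 CPM in sgCTR against 25.5 and 19.2. The list of lipid-associated macrophage genes had a median log2 ratio of −1.03, below all 10000 random lists matched on expression, and 13 of its 15 members were lower by at least 1.5-fold, among them Gpnmb (1250, 596 and 300 CPM), Cd36 (1112, 451 and 324) and Fabp4 (157, 96.1 and 28.5). The list's median was −0.74 in hashtag 1 alone and −1.44 in hashtag 2 alone. Not all of its members fell in every group of cells. Plin2 was among the leading genes of a macrophage cluster with 390 cells of hashtag 1 and 79 of sgCTR.

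The other macrophage genes with the lowest ratios were Saa3, an acute-phase protein (−2.66), Wfs1 (−2.49), the gelatinase Mmp9 (−1.96), Mmp19 (−1.89) and the proteoglycan Gpc1 (−1.85). All 10 lay below sgCTR in both sgMif samples. Both comparisons share the 1 sgCTR sample, though, so this count is no evidence of a shared change. Samples simulated with no difference between genotypes gave 10 of 10 as well. That simulation gave all genes 1 common spread, and for the highest genes it gave 9.95 where 3 were seen. It therefore does not settle how often 10 of 10 arises without a difference.

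Interferon-gamma targets and MHC class I genes were higher in both sgMif samples. The interferon gamma response had a median log2 ratio of 0.90, with 17 of 19 members higher by at least 1.5-fold, and its median was 1.00 in hashtag 1 alone and 0.94 in hashtag 2 alone. Gbp4, a guanylate-binding GTPase, stood at 13.7, 55.5 and 44.8 CPM in sgCTR, hashtag 1 and hashtag 2, and Gbp7 at 39.4, 136 and 88.5, whereas the chemokine Cxcl9 was lower with hashtag 1 (22.4) and higher with hashtag 2 (343) than in sgCTR (103). The MHC class I list had a median of 0.54, with H2-Q6 at 36.6, 252 and 120, H2-Q7 at 137, 609 and 323, and the peptide transporter Tap1 at 106, 268 and 212. Each of these lists lay above all random lists in the pooled sum and in each sgMif sample.

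Other programmes were higher mainly in 1 sgMif sample. With hashtag 1, macrophages held inflammatory and neutrophil-attracting transcripts, with Cxcl3 at 5479 CPM (411 in sgCTR, 190 with hashtag 2), Il1b at 3388 (621 and 1163), Cxcl1 at 1153 (138 and 53.8), Il1a at 594 (47.7 and 32.5), Il6 at 141 (6.90 and 6.63) and the collagenase Mmp8 at 555 (41.0 and 43.0). The median of pro-inflammatory macrophage genes was 1.40 in the pooled sum, 2.13 with hashtag 1 and 0.56 with hashtag 2, and that of NF-kB targets 0.57, 0.99 and 0.07. Hypoxia and glycolysis genes had medians of 0.31, 0.82 and 0.16, and Vegfa stood at 768 with hashtag 1 against 312 in sgCTR and 364 with hashtag 2. Neutrophil RNA in the class was not separated from these values. A macrophage sub-cluster led by S100a9, S100a8 and Retnlg held 3.55% of the macrophages with hashtag 1, 1.48% of sgCTR and 0.408% with hashtag 2. Most macrophages with hashtag 1 (390) lay in cluster 11, whose class is less sure. Its macrophage marker score was 1.44, with neutrophil second at 0.769. The score was 3.38 in cluster 0, 3.12 in cluster 1 and 1.52 in cluster 3. All 11 macrophage markers were detected in cluster 11.

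With hashtag 2, macrophages held monocyte genes, MHC class II genes and monocyte chemokines. The boundary between the classes bears on this, since 751 cells with hashtag 2 were named monocytes at clustering resolution 2, against 171 here. The boundary moved in sgCTR too, with 370 monocytes against 94, and little with hashtag 1 (29 against 21). Ccr2, the receptor that brings monocytes into tissue, stood at 397 CPM with hashtag 2, 86.7 in sgCTR and 11.4 with hashtag 1, and Plac8 at 1302, 365 and 64.0. Ccl12 stood at 406, 71.3 and 9.24, Ccl8 at 323, 47.1 and 4.87, and Gatm, an enzyme of creatine synthesis with the highest pooled ratio (2.80, interval 2.71 to 2.89), at 519, 55.2 and 16.8. The medians with hashtag 1 and hashtag 2 were −2.51 and 1.58 for the monocyte list, −0.65 and 0.93 for MHC class II presentation, −0.20 and 1.19 for type I interferon response, −1.31 and 1.04 for cell cycle, −1.07 and 0.53 for alternatively activated macrophage genes and −1.73 and 0.23 for C1q and efferocytosis. Arg1, an arginine-metabolising enzyme of that alternatively activated list, was higher in both samples (2407 with hashtag 1 and 1815 with hashtag 2 against 564). The cell cycle genes Ccnd1 (log2 ratio 1.82) and Ccnd2 (1.98) and the protease inhibitor Spint1 (2.21) were high with hashtag 2 and at or below sgCTR with hashtag 1. The collagenase Mmp13 was higher in both samples (223 and 464 against 76.9; log2 ratio 2.35).

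**Figure D2:**
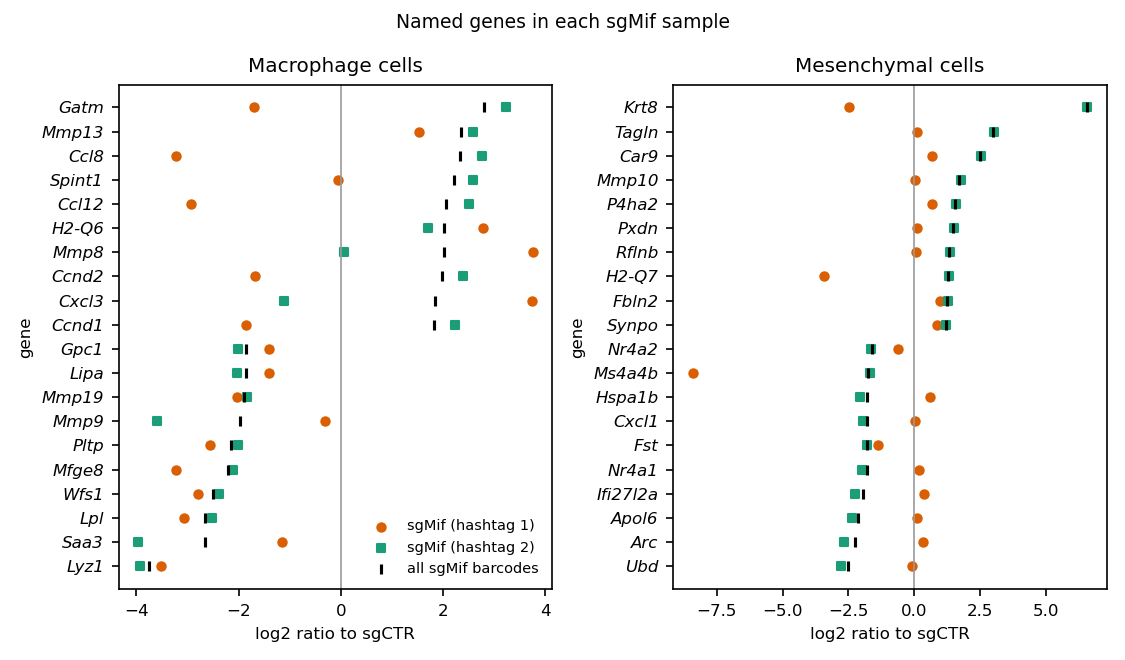
Log2 ratio to the sgCTR sample (x axis) of the 10 genes with the highest and the 10 with the lowest pooled ratio in macrophages and in mesenchymal cells (y axis), for each sgMif sample and for all sgMif barcodes together. In macrophages the genes with the lowest ratios, such as Lpl (−2.65) and Lyz1 (−3.76), lie below sgCTR in both samples, and the points of both samples part for Gatm, Ccl8, Ccl12 and Cxcl3.

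Of the 10 macrophage genes with the highest pooled ratios, 3 (Mmp13, H2-Q6 and Mmp8) lay above sgCTR in both sgMif samples, against a mean of 9.95 in samples simulated with no difference between genotypes and with the spread that edgeR fitted. A test of the 1 sgCTR sample against both sgMif samples with edgeR's quasi-likelihood model, added after the hashtags were read, called 0 of 12384 macrophage genes at an adjusted p of 0.05 (198 at an unadjusted p under 0.05). DESeq2's Wald test called 3 and edgeR without a filter on low counts 20. This design detects little. In macrophage sums simulated with the spread that edgeR fitted, it recovered 48.5% of 8-fold, 10.4% of 4-fold and 1.49% of 2-fold changes, so its count of 0 does not show that genes were unchanged. In the same design limma's camera placed the interferon gamma response first of 23 lists, with its preset correlation and with an estimated one. Whether it called any list depended on that setting. With an estimated correlation it called none. That outcome decides nothing, since 3 sums in 2 groups leave almost no spread from which to estimate a correlation.

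The macrophages of the samples lay in different clusters, which bears on every macrophage value here. Cluster 1, led by Gpnmb, Mfge8, Spp1 and Lpl, held 1220 of the 2497 sgCTR macrophages and cluster 3, led by Lpl, Fn1 and Lyz1, held 788, cluster 11, led by Nos2, Ptges and Cxcl3, held 390 of the 563 with hashtag 1, and cluster 0, led by Ccl12, Gatm and Ms4a4c, held 1379 of the 1959 with hashtag 2. Lyz1 and Lyz2, H2-Q6 and H2-Q7, Ccl8 and Ccl12, Hspa1a and Hspa1b, Mt1 and Mt2 and the Gzmc to Gzmg genes have close copies whose short 3′ reads the counting can split or lose, so the division within each set is uncertain.

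**Figure D3:**
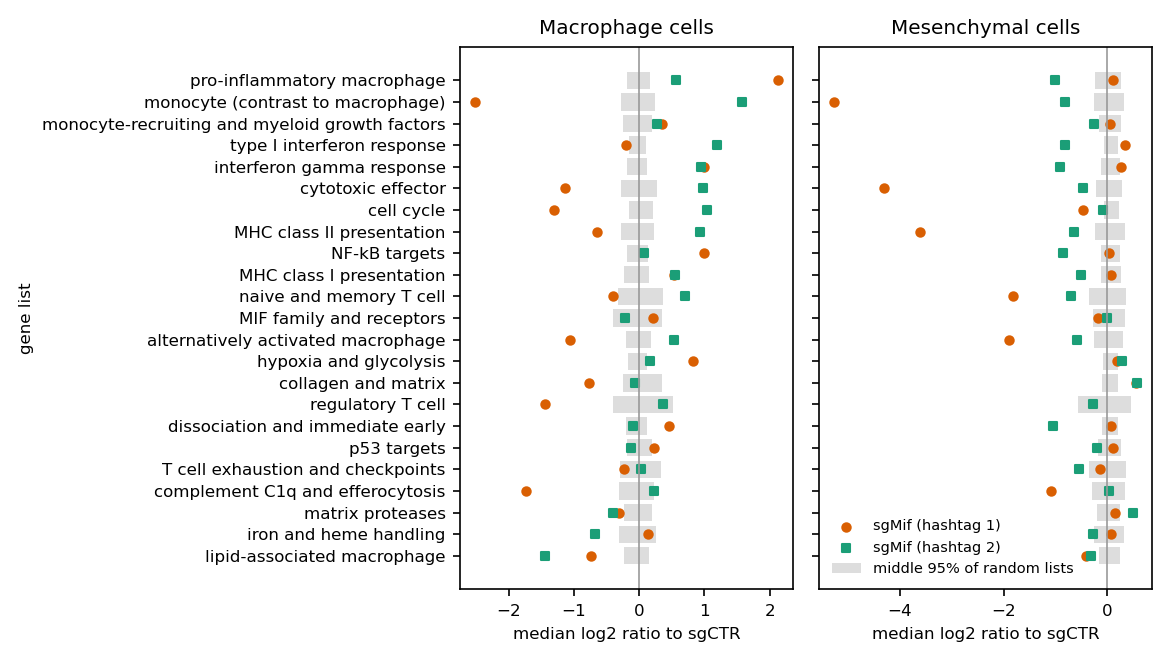
Median log2 ratio to sgCTR (x axis) of each fixed gene list (y axis) in macrophages and mesenchymal cells, for each sgMif sample, with the middle 95% of 10000 random lists for the pooled sums in grey. In macrophages both samples lie right of the grey bars for the interferon gamma response (1.00 and 0.94) and left of them for lipid-associated macrophage genes (−0.74 and −1.44), and they lie on opposite sides for monocyte and cell cycle genes.

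Macrophage heterogeneity itself was compared by clustering the macrophages again without the genes that differed between the pooled genotypes. Genes that differed mainly in 1 sgMif sample, such as Il6, stayed in and could still define the groups. A sub-cluster led by Ccl6, Wfdc17, Trf and Mmp12 held 45.6% of sgCTR macrophages, 26.6% of those with hashtag 1 and 16.5% of those with hashtag 2, and one led by Timp1, Tppp3 and Slpi held 31.2%, 9.59% and 9.29%. A sub-cluster led by Csf3, Il6 and Tnf held 57.7% of the macrophages with hashtag 1, against 2.56% of sgCTR and 0.0510% with hashtag 2. Those led by Cd72, C1qa and H2-Eb1 and by Nr4a3, Nrg1 and Dusp2 held 34.5% and 32.5% with hashtag 2, 5.37% and 10.3% in sgCTR, and 0.888% and 0.355% with hashtag 1. A cycling sub-cluster (Top2a, Mki67) held 0.921% of sgCTR and 2.86% with hashtag 2, and none of the 563 macrophages with hashtag 1 (exact binomial upper limit 0.653%). This 0 does not settle whether cycling cells were absent. Mki67 itself had 46 UMIs in 31 of the 563 macrophages with hashtag 1 and 136 UMIs in 60 of the 2497 of sgCTR. Other cell cycle genes had few UMIs with hashtag 1, with Plk1 at 1 (35 in sgCTR), Bub1 at 4 (31) and Tyms at 16 (68). The cell cycle list lay below sgCTR with hashtag 1, as given above. The class also held a sub-cluster led by the lymphocyte genes Nkg7, Trbc2 and Cd3d (2.24% of sgCTR, 0.533% with hashtag 1 and 1.94% with hashtag 2) and one led by the collagens Col1a2 and Col1a1 (0.360%, 0.710% and 1.94%), besides the S100a9 one above, so other cells or their RNA are part of it.

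**Figure D4:**
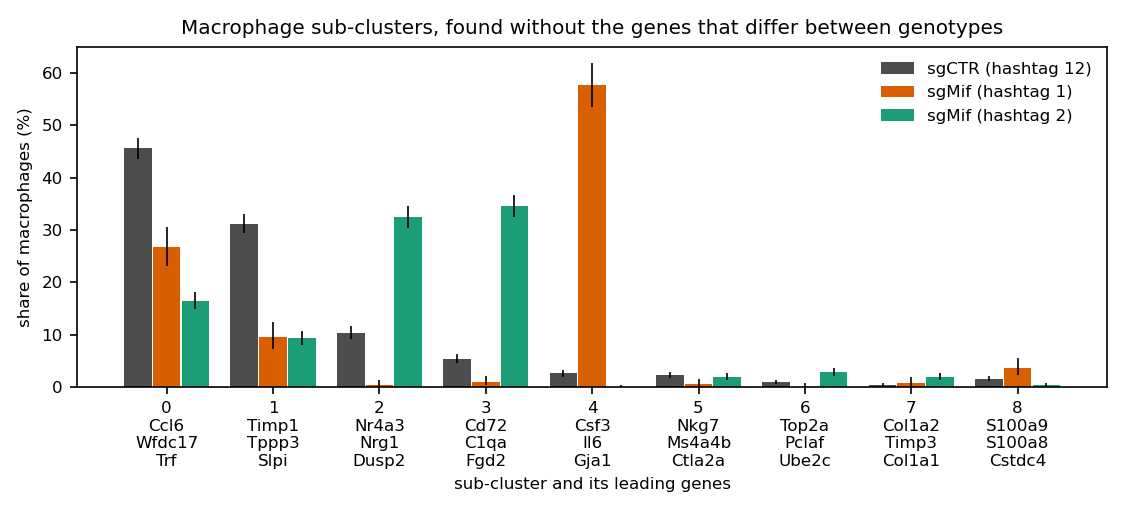
Share of macrophages (percent, y axis) in each of the 9 sub-clusters, found without the genes that differ between genotypes (x axis, number and leading genes), in the 3 hashtag samples, with exact binomial 95% intervals. The sub-clusters led by Ccl6 and by Timp1 held more of sgCTR than of either sgMif sample, and the one led by Csf3 and Il6 held 57.7% of the hashtag 1 macrophages.

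With all variable genes, the choice set beforehand, 54.5% of macrophages would have to change sub-cluster for the sgMif make-up to match that of sgCTR. Without the genes that differ between the pooled genotypes it was 49.2% of macrophages, and the next distances are from that clustering. That distance was 57.6% from sgCTR to hashtag 1 and 54.8% from sgCTR to hashtag 2, and it was 71.3% between both sgMif samples, which carry the same guide. The reactions lay 3.74% apart within sgCTR and 7.52% within sgMif. In that clustering the difference between genotypes was therefore larger than the difference between capture reactions and smaller than the difference between the sgMif samples. The order of the samples depended on the processing. With all variable genes and Scrublet, hashtag 1 lay 72.1% from sgCTR and 63.2% from hashtag 2, and hashtag 2 lay 57.8% from sgCTR. Without the genes that differ between any samples, hashtag 1 lay 50.2% and hashtag 2 48.8% from sgCTR. The sgMif samples then lay 66.1% apart.

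In mesenchymal cells matrix genes were higher in sgMif and inflammatory and immediate early genes lower. The red fluorescent reporter was read in 216 of 383 sgCTR cells and 291 of 619 with hashtag 2 (59.6 and 39.1 CPM), so the share of host cells in the class is open and not known to be equal. Among cells with a reporter UMI the collagen and matrix median was 0.55 and the immediate early median −1.11. Collagen and matrix genes had a median log2 ratio of 0.59, above all random lists, with 11 of 21 measured members higher by at least 1.5-fold, such as Col6a3 (172 CPM in sgCTR and 400 with hashtag 2) and Col12a1 (6.72 and 19.9). Matrix proteases had a median of 0.49 and included Mmp10 (log2 ratio 1.72). The largest ratio was that of Krt8, a keratin of simple epithelia, with 1.06 CPM in sgCTR and 122 with hashtag 2 (log2 ratio 6.58, interval 5.84 to 7.90), whose 2000 UMIs came from 77 of the 619 hashtag 2 cells. Tagln, an actin-binding protein of smooth muscle, had a log2 ratio of 2.99, Car9, a carbonic anhydrase induced by hypoxia, 2.49, and P4ha2 and Pxdn, both enzymes that modify collagen, 1.57 and 1.48. The others among the 10 highest were Rflnb (1.33), H2-Q7 (1.29), Fbln2 (1.25) and Synpo (1.21).

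Dissociation and immediate early genes had a median of −1.01, with 15 of 20 measured members lower by at least 1.5-fold. Nr4a1 stood at 474 CPM in sgCTR and 120 with hashtag 2 (log2 ratio −1.81), Atf3 at 259 and 83.6, and Hspa1b, a heat shock protein, at 316 and 74.9 (−1.79). This list also responds to how a tumour is dissociated. The interferon gamma response had a median of −0.81 with 16 of 19 members lower by 1.5-fold, the type I interferon response −0.72, NF-kB targets −0.78 and MHC class I presentation −0.49. Ifi27l2a, an interferon-induced gene, stood at 2717 and 575 CPM (−1.95), Cxcl10 at 1260 and 428, Gbp4 at 54.7 and 17.7 and Cxcl1 at 436 and 113 (−1.80). The other genes with the lowest ratios were Ubd (−2.50), Arc (−2.27), Apol6 (−2.13), Fst (−1.80), the lymphocyte gene Ms4a4b (−1.74) and Nr4a2 (−1.61). Hypoxia and glycolysis had a median of 0.27 and cell cycle −0.10.

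The mesenchymal values rest on hashtag 2. Of the 44 mesenchymal barcodes called sgMif by hashtag 1, 41 carried more counts of hashtag 12, the sgCTR tag, than of hashtag 1. In these barcodes Krt8 was at 0, Ifi27l2a at 3545 and Nr4a1 at 537 CPM, all near sgCTR, and the interferon gamma median was 0.26, whereas the collagen median was 0.55. Of the 10 lowest genes 4 lay below sgCTR with both hashtags, and of the 10 highest 8 lay above it, against simulated means of 9.49 and 9.76. RNA of immune genes was read in the class and differed between samples, with Cd74 at 476 CPM in sgCTR, 25.4 with hashtag 1 and 305 with hashtag 2, and the lists of monocyte genes (median −0.88) and of naive and memory T cell genes (−0.77) lay below the middle 95% of random lists. In the mesenchymal cells with few immune UMIs, the interferon gamma median was −1.05, the immediate early median −1.05, the NF-kB median −0.46 and the collagen median 0.48.

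The added 3-sample edgeR test called 3 of 12775 mesenchymal genes. Krt8 (log2 fold change 5.98 ± 1.09 SE, adjusted p = 0.0384) and Ptn, a heparin-binding growth factor (4.57 ± 0.834 SE, adjusted p = 0.0384), were higher with hashtag 2 and had 0 and 2 UMIs with hashtag 1, and Retnla (−7.02 ± 0.996 SE, adjusted p = 0.00202) was lower with both. All 140 Retnla UMIs of sgCTR came from 4 of 383 cells, 115 of them from 1 cell, so this call rests on a few barcodes. DESeq2's Wald test called 0, with 23 at an unadjusted p under 0.05. Because the hashtag 1 barcodes of this class carry mostly the sgCTR tag, this test does not compare 2 sgMif samples with 1 sgCTR sample. Most sgCTR mesenchymal cells (200 of 383) lay in cluster 10, led by the cycling genes Ube2c and Cdk1, and most of the hashtag 2 cells (330 of 619) in cluster 8, led by Ogn, Col3a1 and Aspn.

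Neutrophils of the hashtag 1 sample, which were most of its cells, had more RNA of hypoxia genes and NF-kB targets than those of sgCTR, a difference that no test supports. The genes with the highest pooled ratios were Csf3 (log2 ratio 2.94), which encodes the growth factor G-CSF, Pwp1 (2.93), the stress cytokine Gdf15 (2.85), the nitric oxide synthase Nos2 (2.33) and Fam71f2 (2.24). Nos2 stood at 303 CPM with hashtag 1, 52.6 in sgCTR and 3.55 with hashtag 2. The genes with the lowest ratios were Lrg1, a granule protein of neutrophils (587 in sgCTR, 135 and 139 in the sgMif samples, log2 ratio −2.10), Gm26917 (−1.87), Ripor2 (−1.82), Adam30 (−1.68) and Lbr (−1.67). Hypoxia and glycolysis genes had a median of 0.85 with hashtag 1, where 16 of 20 measured members were higher by at least 1.5-fold, and −0.98 with hashtag 2. NF-kB targets were at 0.84, with 10 of 18 members higher by as much, and at −0.64. With hashtag 1 both medians lay above the middle 95% of random lists, and with hashtag 2 that of NF-kB targets lay within it. Only 103 neutrophils carried hashtag 2, and cluster 2 (Lcn2, Ccl3, Slpi) held 1232 of the 1504 neutrophils with hashtag 1 whereas cluster 5 (S100a9, Retnlg) held 303 of the 534 in sgCTR. The 3-sample edgeR test called 0 of 6334 genes (77 at an unadjusted p under 0.05, and 0 with DESeq2's Wald test), and recovered 34.8% of simulated 8-fold changes. In the same design camera called 0 of 23 lists even with its preset correlation (smallest adjusted p = 0.258).

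T cells of both sgMif samples held fewer heat shock and immediate early transcripts. Hspa1a stood at 544 CPM in sgCTR, 175 with hashtag 1 and 96.1 with hashtag 2 (log2 ratio −2.45), and Hspa1b at 810, 200 and 169 (−2.24). Dissociation and immediate early genes had a median of −0.31, below all random lists, and it was −0.55 with hashtag 1 and −0.34 with hashtag 2. Cd163l1, a marker of gamma-delta T cells, had the lowest ratio, from hashtag 2 (8.28 CPM against 95.4 in sgCTR and 95.2 with hashtag 1), and Tmem176a (−1.86) and Tagap (−1.85) came next. Gzmf had the highest ratio (6.62), but its 1305 UMIs with hashtag 2 came from 29 of 1386 cells, and those of Gzmc (1.51) with hashtag 1 from 6 of 47 cells. The NK receptor gene Klra7 (1.75) and Ier5l (1.60) were also high with hashtag 2, and so was Arg1 (2.90), a gene abundant in macrophages, with 332 UMIs in 62 of 1386 cells. The type I interferon response had a median of 0.53, at 0.56 with hashtag 2 and −1.44 with hashtag 1.

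The 3-sample edgeR test called 17 of 10474 T cell genes, 13 higher and 4 lower. This balance is not stable, since 4 were higher and 5 lower in reaction 2 alone, and 2 higher and 24 lower with the reaction as a replicate block. Of the 47 T cells with hashtag 1, 6 carried more of the sgCTR tag. In simulated T cell sums the test made 11 false calls. It recovered 56 of 66 changes of 8-fold, 23 of 67 of 4-fold and 1 of 67 of 2-fold. Its adjusted p-values in this class may therefore be too small. The called genes included Hspa1a (log2 fold change −2.07 ± 0.427 SE, adjusted p = 0.00131) and Hspa1b (−2.15 ± 0.416 SE, adjusted p = 0.000368), both lower in each sgMif sample. The higher ones included the neutrophil markers S100a9, Il1r2 and G0s2, with S100a9 at 1147 CPM in the 47 T cells of the neutrophil-rich hashtag 1 sample, 116 in sgCTR and 154 with hashtag 2. The count was 0 in reaction 1 alone and 0 with DESeq2's Wald test. Cluster 6 (Cd4, Rora, Tnfsf11) held 339 of the 891 sgCTR T cells and 34 of the 47 with hashtag 1, and cluster 4 (Ikzf2, Klra7, Trdc) held 574 of the 1386 with hashtag 2.

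NK cells could in effect be compared only between sgCTR (412 cells) and hashtag 2 (616 cells), since 10 carried hashtag 1. The log2 ratios and medians here are of all sgMif NK cells, with these 10 and 15 tied to neither tag included. Metallothioneins Mt2 (log2 ratio 2.33) and Mt1 (2.23), the chemokine Cxcl10 (2.25), granzyme Gzmg (2.04) and Gm47283 (1.31) had the highest ratios. Gzmg had 1628 UMIs with hashtag 2, from 44 of 616 cells and 428 of them from 1 cell. Hspa1b (−1.51), Hspa1a (−1.51), Ifng (137 CPM in sgCTR and 68.1 with hashtag 2), Egr1 (−0.85) and Tmem176b (−0.77) had the lowest. Hypoxia and glycolysis genes had a median of 0.50, above all random lists, and the MHC class II list a median of 1.31, where 5 of the 616 hashtag 2 cells held 88.2% of H2-Aa, 92.2% of H2-Eb1 and 82.4% of Cd74 UMIs. No test was run on NK cells.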

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

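Of the tests below, the one of nonspecific hashtag binding was set before its result was seen, and the tests of the gene minimum, CD45 enrichment, reporter-positive cells, the edited transcript and the hashtag 1 mesenchymal barcodes were chosen after the results were seen.

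Neutrophils made up 68.1% of the sgMif sample with hashtag 1 and 1.93% of the one with hashtag 2, although both carry the same guide. Binding of hashtag 1 to neutrophils of other samples is argued against, since 15.6% of neutrophil barcodes with at least 50 counts of hashtag 1 also carried at least 50 of hashtag 2 or 12, against 43.3% of macrophage barcodes, with uncalled barcodes included in both. The gene minimum and unequal CD45 enrichment are argued against too, since the ratio of both shares was 30.1 with a minimum of 200 genes and 30.8 among immune cells. A difference between individual tumours, such as necrosis, ulceration or infection, or in their handling, may account for it and was not tested, because each sample exists once. The pooled sgMif values for neutrophils and for inflammatory macrophage genes follow this 1 sample.

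Mif RNA was not lower in mesenchymal cells called sgMif. Dilution by host mesenchymal cells without the guide is argued against, since the log2 ratio was 0.23 among mesenchymal cells with a UMI of the red fluorescent reporter. An indel that changes the protein and leaves the 3′ end of the transcript may account for it, with a log2 ratio of 0.20 over all mesenchymal cells, and cannot be told apart from an unedited gene in these counts. The files hold no protein measurement of MIF and no reads over the guide's site.

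Mesenchymal barcodes called sgMif by hashtag 1 differed from those with hashtag 2 in Krt8, Ifi27l2a and Nr4a1. Of these 44 barcodes, 93.2% carried more counts of hashtag 12, the sgCTR tag, than of hashtag 1, against 0.969% of the hashtag 2 mesenchymal barcodes, 2.31% of the hashtag 1 macrophages, 6 of its 47 T cells and 5 of its 10 NK cells. Of the genes 2-fold apart between hashtag 2 and sgCTR, 85.3% lay nearer sgCTR in these barcodes. Other values did not match sgCTR, with a collagen median of 0.55 and 3 H2-Q7 UMIs in 44 barcodes against 459 in the 383 sgCTR ones. Cd74 had 16 UMIs against 4035, but the sgCTR sum may hold RNA of immune cells, so this gap decides nothing. Xist RNA, at 761 CPM in sgCTR macrophages, was at 85.8 in all sgCTR mesenchymal cells. It was at 1.70 in the sgCTR ones with few immune UMIs and at 6.50 in the hashtag 1 barcodes. Whether the H2-Q7 UMIs of sgCTR also come from immune cells was not tested. The hashtag counts are thus consistent with sgCTR cells called sgMif in this class and the expression only in part, as a hypothesis found and tested on the same data.

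The red fluorescent reporter, an added sequence used above to choose cells, was read at 59.6 CPM in sgCTR mesenchymal cells, 84.5 in the hashtag 1 ones and 39.1 in the hashtag 2 ones, and at 0 to 0.579 in macrophages, neutrophils, T cells and NK cells. The green reporter had 0 UMIs in all 5 classes.

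Of the barcodes without a genotype call, 6982 passed the cell filters. By the nearest cluster, 42.9% of them were macrophages, 17.9% mesenchymal cells (against 373 of 4975 sgCTR cells and 682 of 7757 sgMif cells placed in the same way), 11.8% neutrophils and 6.75% fibroblasts. At least 50 counts of 2 or more hashtags were on 25.6% of them, and 22.7% had under 50 of every hashtag. In 82 called barcodes hashtag 3 (50) or 4 (32) was the highest, and all were called sgMif. The labels list these tags, and whether they mark further sgMif samples is not stated.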

How the results depend on the processing

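The division of sgMif cells by hashtag, the 3-sample test made possible by it, mesenchymal cells with few immune UMIs or with a reporter UMI, and the clustering without genes that differ between any samples were chosen after seeing the data. The alternatives of a test and of leaving out a sample had been listed before, on the condition that the data allowed them, and the other alternatives were set before. Where a value below moved, the cause was not tested unless a cause is named.

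Nearly all named genes held their direction unless an sgMif sample was left out. Of 905 values of named genes in settings that keep both sgMif samples, 893 had the same direction and 3 reversed. The remaining values lost the direction without being counted as reversed. The genes with the highest and lowest ratios were chosen for being at least 1.5-fold apart in the same direction in each reaction. Their values with a reaction left out could therefore not reverse, are part of this count and test nothing. Of 95 results for named genes, 26 reversed without 1 of the sgMif samples, because those samples differ. The ranges that follow are over leaving out each reaction and each sgMif hashtag.

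Pooled share differences, in points of sgMif minus sgCTR, ranged from −8.80 to 57.4 for neutrophils, −24.7 to −13.4 for macrophages, −15.8 to 8.11 for T cells, −7.83 to 3.28 for NK cells and −5.71 to 3.92 for mesenchymal cells. Among immune cells they ranged from −9.42 to 58.2 for neutrophils and −17.3 to 11.0 for T cells. With at least 1000 genes per cell they were 0.148 for neutrophils, −24.0 for macrophages, 5.56 for T cells, 1.40 for NK cells and 3.06 for mesenchymal cells. With at least 200 genes they were 16.7 for neutrophils, −19.8 for macrophages and −1.06 for T cells (−0.615 among immune cells). Macrophages were at −19.5 with 4000 variable genes, −23.5 with Scrublet and −13.6 at resolution 2. The pooled macrophage difference thus stayed negative in every setting, and the neutrophil difference did not keep its sign. In the hashtag 1 sample alone macrophages were higher than sgCTR with at least 1000 genes (66.5% against 47.5%), where few of its neutrophils remain. Clusters left without a name held 974 of 5366 sgMif and 321 of 3850 sgCTR cells in that setting, 955 of 7428 and 318 of 4732 with Scrublet, 643 of 7757 and 261 of 4975 with 4000 variable genes and 314 and 429 at resolution 2, so the class shares of these settings are uncertain, most of all with hashtag 2 (961 of 4538 cells unnamed with at least 1000 genes and 942 of 5054 with Scrublet). Depth limits the shares, since a minimum number of genes removes neutrophils first.

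The log2 ratio of Mif in macrophages was 0.57 with Scrublet, 0.52 at resolution 2 and 0.48 with total counts (range 0.17 to 0.91). In mesenchymal cells the log2 ratio of Mif was 0.14 with DESeq2 size factors, 0.11 with Scrublet, 0.23 in cells with a reporter UMI and 0.022 in cells with few immune UMIs (range 0.0045 to 0.23). In neutrophils Mif ranged from −0.79 to 1.29 and Ddt from −0.35 to 1.22.

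Macrophage log2 ratios ranged from −1.71 to 3.19 for Gatm, −3.23 to 2.73 for Ccl8, −2.92 to 2.46 for Ccl12, −1.85 to 2.19 for Ccnd1, −1.67 to 2.36 for Ccnd2, −1.16 to 3.74 for Cxcl3 and −0.045 to 2.54 for Spint1. Mesenchymal log2 ratios ranged from −1.77 to 7.0 for Krt8, −3.39 to 1.49 for H2-Q7, −2.38 to 0.12 for Apol6, −2.66 to 0.34 for Arc, −2.25 to 0.046 for Cxcl1, −2.07 to 0.60 for Hspa1b, −2.24 to 0.38 for Ifi27l2a and −2.05 to 0.18 for Nr4a1. In mesenchymal cells with few immune UMIs Cd74 was at 0.21 and Ms4a4b at 0.43, but Cd74 is 1 of the 10 genes by which these cells were chosen, so its value there tests nothing. Neutrophil ratios ranged from −3.11 to 2.52 for Nos2, −0.13 to 3.25 for Pwp1, −0.18 to 2.40 for Fam71f2 and −2.45 to 0.17 for Gm26917. T cell ratios ranged from −1.22 to 7.42 for Gzmf, −0.33 to 2.95 for Arg1, −0.46 to 1.98 for Ier5l, −0.51 to 1.98 for Klra7 and −2.40 to 1.51 for Tmem176a. In NK cells Cd74 ranged from −0.018 to 3.17 and Mt2 from 1.04 to 3.09.

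Medians of macrophage lists ranged from −2.51 to 1.58 for monocyte genes, −1.31 to 1.04 for cell cycle, −1.07 to 0.57 for alternatively activated genes, −0.65 to 0.93 for MHC class II and −0.20 to 1.19 for type I interferon. Medians of mesenchymal lists ranged from −1.06 to 0.26 for interferon gamma, −0.81 to 0.33 for type I interferon, −1.07 to 0.072 for immediate early genes, −0.85 to 0.023 for NF-kB, −0.57 to 0.075 for MHC class I and −0.47 to 0.077 for cell cycle. In neutrophils they ranged from −0.64 to 0.87 for NF-kB and −0.98 to 0.85 for hypoxia, and in T cells from −1.44 to 0.63 for type I interferon. In the reported setting 3 of 23 fixed lists lay above and 16 below the random range in mesenchymal cells. In neutrophils 7 of 18 lay above and 3 below. Lists outside the range were 11 in mesenchymal cells with few immune UMIs, 6 in neutrophils with Scrublet and 4 to 12 in neutrophils over the samples left out. With an estimated correlation camera called no list. This tests nothing, since the design leaves almost no spread from which to estimate a correlation.

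The edgeR count of T cell genes was 17 and became 0 with DESeq2's Wald test, 9 with Scrublet, 8 under 5% mitochondrial UMIs and 0 to 9 in single reactions. Its 13 higher and 4 lower genes became 4 and 5 in reaction 2 alone and 2 and 24 with the reaction as a replicate block, so the balance of higher and lower genes was not stable. The macrophage count of 0 became 3 with the Wald test and 20 without a filter on low counts. The mesenchymal count of 3 became 0 with the Wald test, 6 with DESeq2 size factors, 18 with Scrublet, 20 without the filter, 11 at resolution 0.5, 11 under 20% mitochondrial UMIs and 1 to 16 in single reactions. The neutrophil count was 0 to 3. With the reaction as a replicate block the count was 26 in T cells, 29 in mesenchymal cells and 0 in macrophages, and these repeats of 1 pool add no animals.

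The distance of sgMif from sgCTR over macrophage sub-clusters was 57.0% with 4000 variable genes, 59.2% with Scrublet, 50.6% with at least 1000 genes, 52.0% at sub-cluster resolution 0.3 and 60.8% at 1, 49.2% without genes that differ between genotypes and 45.4% without genes that differ between any samples (range 53.5% to 73.5%).

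The 3-sample test was not run for NK cells or for mesenchymal cells under 5% mitochondrial UMIs, since hashtag 1 held fewer than 30 cells. Leaving out an sgMif hashtag leaves 1 sample against 1 and no test. The filter on low counts does not move the ratios. Thinning of UMIs was not run. Numbers of cells with a UMI are given mostly to show how few cells hold a sum. Those of the red fluorescent reporter and of Mki67 are also set side by side for the samples. Without thinning they do not measure a difference between samples.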

Other observations

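The genes of this part were picked after their levels were seen, and no tests were run for it beyond the 3-sample edgeR test named below. Interleukin 17 transcripts marked a small group of T cells, rarer with hashtag 2 than in the other samples. Cluster 20, led by Cd163l1, Trdc and Il17a, genes of gamma-delta T cells that make interleukin 17, held 68 of the 891 sgCTR T cells, 5 of the 47 with hashtag 1 and 2 of the 1386 with hashtag 2. In T cells Il17a was at 66.1 CPM in sgCTR, 712 with hashtag 1 and 9.39 with hashtag 2, and 100 of the 133 Il17a UMIs with hashtag 1 lay in 1 cell. Il17a is among the 17 T cell genes that the 3-sample edgeR test called (log2 fold change 2.25 ± 0.493 SE, adjusted p = 0.00435), a call that rests on the hashtag 1 sample, since the level with hashtag 2 was below sgCTR. Trdc, the constant region of the delta chain, was at 210, 112 and 121 CPM. NK cells with hashtag 2 also held Trdc (63.4 CPM), so Trdc RNA alone does not mark gamma-delta T cells here.

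Granzyme sums of NK cells differed between sgCTR and hashtag 2. Gzmc was at 12648 CPM in sgCTR and 9298 with hashtag 2, while Gzmd was at 970 and 1717, Gzme at 289 and 657, and Gzmf at 1010 and 2008. The Gzmf sum rests on few cells, since its 7759 UMIs with hashtag 2 lay in 52 of 616 cells and 814 of them in 1 cell. These genes lie in 1 family of close copies, and the reads may be divided wrongly among them. Gzmg had a log2 ratio of 2.09 in NK cells without hashtag 1.

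Xist, the RNA of the inactive X chromosome, was at 761 CPM in sgCTR macrophages, 731 with hashtag 1 and 578 with hashtag 2, and no UMI of the Y-linked genes Ddx3y or Eif2s3y was seen in the 5 large classes. In mesenchymal cells Xist was at 85.8, 6.50 and 32.9 CPM, and in those with few immune UMIs at 1.70 in sgCTR and 0.625 with hashtag 2.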
